A study of Mus musculus with 8 samples.

How the data were processed

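Gene expression was measured in BaF3 cells, a mouse pro-B cell line that needs interleukin-3 to grow, on Affymetrix mouse oligonucleotide arrays. Per the labels, 4 arrays came from cells that carried the empty inducible vector (control), whose genotype is labelled wild type, and 4 from cells that carried TEL-AML1, the fusion of ETV6 and RUNX1 found in childhood B-cell leukaemia. Per the labels' protocols, the vector responds to mifepristone, induction used 0.0125 nM mifepristone for 3 days, cells were kept in hygromycin at 0.2 mg/ml, and the TEL-AML1 clones were in addition kept in Zeocin, so the presence of Zeocin and the group coincide. The same protocol text stands with every sample, and it is not explicit about whether the control cells also received mifepristone. Labelling started from 100 ng of total RNA. Each array was numbered as experiment 1 to 4 within its group, so each number stands for 1 control and 1 TEL-AML1 array. The running numbers in the sample titles alternate between control and TEL-AML1 arrays in the order of the experiment number. The labels do not say whether the 4 arrays of a group came from separate clones or cultures, so p-values measure the spread between these arrays, which may be partly technical.

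The deposited values are log2 expression values per probe set. RMA is named as the processing tool per the submitters' processing notes, and its version is not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays by quantile normalization and summarises the probes of a set, so that a general shift in RNA content per cell is removed and differences near the floor are compressed. The median log2 value per array lay between 4.21 and 4.29. No sequencing depth applies, and the number of arrays limits the precision.

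The table held 45101 probe sets. Of these, 64 were array controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed here. Symbols were looked up through the Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which held 34741 of the probe sets with 1 symbol; it changed no symbol, and the remaining 204 kept the platform's symbol. Each gene was represented by the probe set with 1 symbol that had the highest mean over the 8 arrays, which gave 18193 genes. A background level was set at the 95th percentile of the mean log2 values of 124 probe sets of olfactory, vomeronasal and taste receptor and keratin-associated genes, and equalled 4.79. Where the mean of the lower group lay under that level, a fold change is given as a lower bound against the background level, and 9814 genes had a mean above it.

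Groups were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes, two-sided, on all 8 arrays with group as the single term, and p-values were adjusted by the Benjamini-Hochberg method over all genes. An adjusted p under 0.05 counted as passing, and a log2 difference of at least 1 as a 2-fold change. Differences are TEL-AML1 minus control, given with the standard error (SE) of the fit. Gene lists were fixed before the data were examined: 28 for processes and 9 for cell type markers, with 1521 measured entries of 1640. Entries that were not measured under a single symbol are not analysed here. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01 and adjusted over the 37 lists, of which 1 is not reported here, and again with the correlation estimated for each list. Probe sets of Etv6 and Runx1 were tested in the same way among all probe sets. The difference between 3 prime and 5 prime control probe sets of Gapdh and Actb was tested with an exact two-sided permutation test.

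The genes named were chosen by a rule fixed before the data were examined. In each direction it took the 8 genes with the largest absolute log2 difference that passed, did not overlap between groups and exceeded background in the higher group, passing over clone, RIKEN and Gm names. It added the 3 passing members with the smallest p of each list that passed and of further lists fixed in advance, among them those for human ETV6-RUNX1 leukaemia, chemoattractant receptors, TGF-beta signalling, inflammatory cytokine receptors and B-lymphoid differentiation. It further added the passing member with the smallest p of each other list, Etv6, Runx1 and a fixed set of receptors for chemokine, TGF-beta, activin, interleukin-6, interleukin-1 and TNF whether they passed or not. This gave 96 genes, 5 of them represented by probe sets that may match more than 1 transcript.

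The gene and list tests were tested on simulated data with the real means and spreads of the 18193 genes. Of 50 genes each changed by a log2 difference of 0.5, 1, 2 and 4, 76%, 98%, 100% and 100% were called, and 5% of all calls were false. These changed genes were drawn from genes with a mean above background, so the rates do not apply to dimmer genes. All 10 lists shifted by 0.3 on the log2 scale were called, and none of the unshifted lists. The simulated genes varied independently, so this does not show how often unshifted lists of correlated genes would be called. In the real data the estimated correlation was 0.293 for the ribosome biogenesis list and 0.231 for the p53 list. The alternatives tried were the experiment number as a replicate block, each array left out in turn, a further quantile normalization, centring on the array median, the mean of all probe sets or the most variable one per gene, genes above background alone, eBayes with trend and robust settings, array quality weights, all probe sets as the unit, and other list tests (estimated correlation, fry and ranks). Leaving out probe sets that may match several transcripts, counting 2-fold changes over all probe sets, and leaving out arrays for the probe sets of Etv6 and Runx1 and for the control probe sets were added after the data had been seen.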

Results

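Expression profiles of 8 arrays were compared, 4 from BaF3 cells with the TEL-AML1 fusion and 4 from BaF3 cells with the empty vector. The design asks which genes change when this pro-B cell line carries the fusion. The series title places the question in the setting of inflammation and a mesenchymal niche, so receptors for inflammatory and TGF-beta family signals were among the genes fixed in advance. Correlations between arrays ranged from 0.9956 to 0.9976 within groups and from 0.9825 to 0.9872 between groups, across probe sets, and no pair of arrays was identical. Unless stated otherwise, values are log2 differences ± SE from limma with n = 4 arrays per group, and an adjusted p is the Benjamini-Hochberg value of that fit.

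Transcripts of both fusion partners were more abundant in TEL-AML1 cells. All 6 probe sets of Runx1, a transcription factor required for definitive haematopoiesis, rose, by 1.19 ± 0.09 to 3.61 ± 0.09 where the control mean lay above background and at least 1.28-fold, 4.3-fold and 10.7-fold where it did not. The probe set with the smallest difference (0.36 ± 0.12, adjusted p = 0.0448), whose arrays overlapped between groups, no longer passed without control replicate 2, 3 or 4 or TEL-AML1 replicate 1, 2 or 4, with adjusted p from 0.0722 to 0.126. The Runx1 probe set used for the gene averaged 5.90 ± 0.15 (SD, n = 4) in control and 8.42 ± 0.11 in TEL-AML1 cells, a difference of 2.52 ± 0.09 or 5.74-fold (adjusted p = 4.01e-09). Both probe sets of Etv6, an ETS family repressor, rose, by 1.09 ± 0.12 and 0.89 ± 0.09. The probe sequences were not used here, so it stays open which of these probe sets match the transgene and which the mouse genes.

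**Figure D1:**
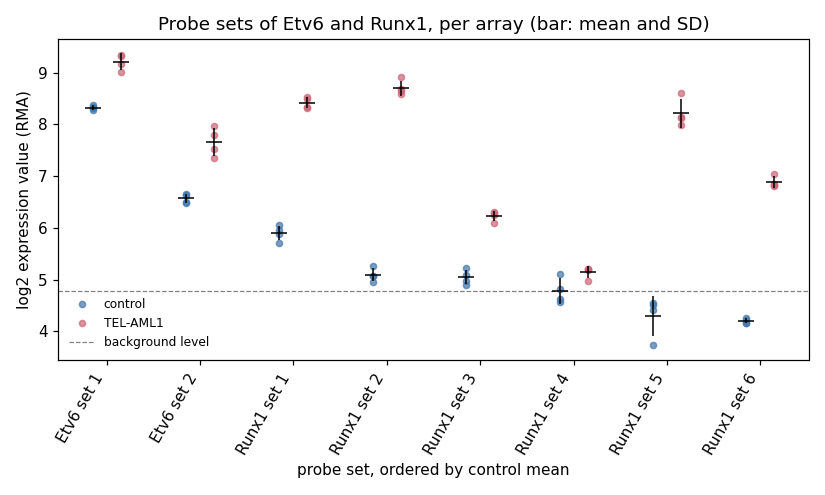
Log2 expression values of the 2 probe sets of Etv6 and the 6 of Runx1 on each of the 8 arrays, with group means and SD as bars and the background level of 4.79 as a dashed line. TEL-AML1 means lie above control means for every probe set, and the individual arrays of the groups overlap for 1 Runx1 probe set, which had the smallest difference of 0.36.

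The largest differences between fusion-carrying and control cells included gains of the eosinophil granule transcripts Prg2 and Epx and losses of the granzymes Gzmb and Gzmc. With control means under background, Prg2 (eosinophil major basic protein) rose at least 41.4-fold and Epx (eosinophil peroxidase) at least 20.9-fold. Siglecf, a lectin on the surface of eosinophils, rose at least 10.3-fold. In the other direction Gzmb, a cytotoxic granule protease and one of the brightest signals in control cells at 14.15 ± 0.03 (SD, n = 4), fell to 5.79 ± 0.26 (adjusted p = 3.24e-12). The measured values differed 328-fold, and the control mean lay close to the highest values of the control arrays, 14.51 to 14.57, where signals can be compressed. Its relative Gzmc fell at least 91.8-fold.

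Among the other genes with large measured rises were the zinc transporter Slc39a8 (5.48 ± 0.15), the seminal vesicle protein gene Svs2 (at least 9.61-fold), the haematopoietic surface receptor Slamf1 (at least 21.2-fold), the complement regulator Cd55 (4.99 ± 0.13) and Csgalnact1, an enzyme of chondroitin sulphate synthesis (at least 19.9-fold). The other genes with large measured falls were the actin-severing protein Scin (at least 99.8-fold), the small GTPase Gem (at least 14.3-fold), Igsf5 (at least 19.2-fold), the proton-sensing receptor Gpr65 (at least 3.5-fold), the short-chain fatty acid receptor Ffar2 (-4.31 ± 0.11) and the forkhead factor Foxs1 (at least 9.51-fold). The highest adjusted p among these 16 genes was 1.21e-07, for Gpr65. In all, 5374 of 18193 genes passed, 2628 of them higher and 2746 lower in TEL-AML1 cells. Changes of at least 2-fold were more often rises, with 486 genes higher and 191 lower.

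**Figure D2:**
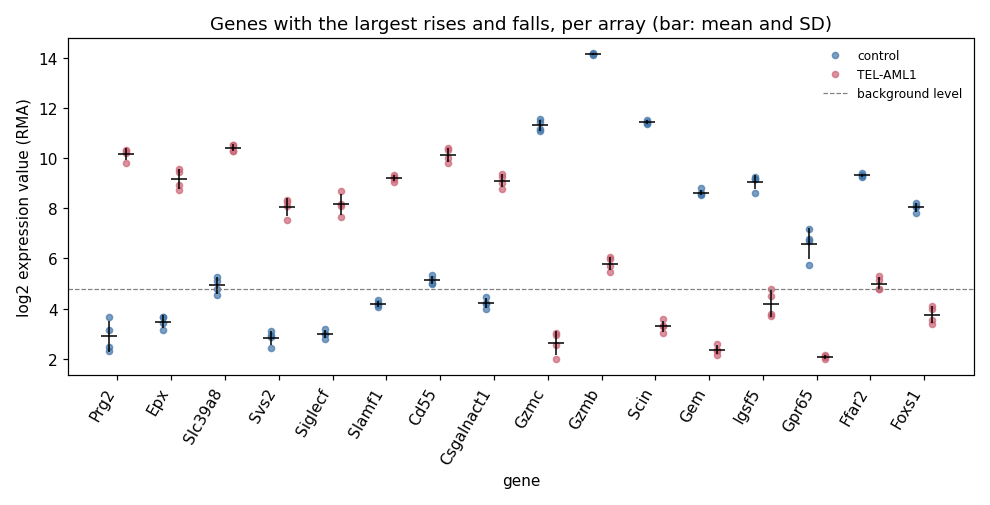
Log2 expression values per array of the 8 genes with the largest rises and the 8 with the largest falls by measured log2 difference, with group means and SD as bars and the background level of 4.79 as a dashed line. No control array overlaps a TEL-AML1 array for any of these genes; Prg2 averages 2.90 in control and 10.16 in TEL-AML1, and Gzmb 14.15 and 5.79.

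Genes of ribosome biogenesis fell together. Of 56 measured members of this MYC-associated list, 40 fell, none rose and 16 did not pass; adjusted over the list alone, 44 fell. Mycn, a MYC family factor, fell by 1.85 ± 0.12, the nucleolar protein gene Noc2l by 1.04 ± 0.08 and Fbl, the methyltransferase of ribosomal RNA, by 0.74 ± 0.08, the last on a probe set that may match more than 1 transcript. The list median was -0.34, and camera gave an adjusted p of 2.09e-11 with the preset correlation and adjusted p = 0.318 with an estimated correlation.

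Among target genes of p53, cell-cycle brakes and genes of cell division, more members rose than fell. Of 45 measured p53 targets, 23 rose, 3 fell and 19 did not pass (23 and 4 adjusted over the list alone), with a median of 0.30. Of these members, 14 also stand in another list. Gadd45a, a growth-arrest and DNA-damage gene, rose by 1.94 ± 0.16, Zmat3 by 1.76 ± 0.13 and Ptprv by 0.74 ± 0.07. The camera adjusted p of this list was 3.09e-06, and adjusted p = 0.318 with an estimated correlation. Of 29 cell-cycle brakes, 13 rose, 3 fell and 13 did not pass (13 and 4 adjusted over the list alone), with a median of 0.06. The cyclin-dependent kinase inhibitors Cdkn1a and Cdkn2c rose by 1.06 ± 0.12 and 1.04 ± 0.08, whereas the MYC antagonist Mxi1 fell by 0.76 ± 0.08 (camera adjusted p = 0.00666, and adjusted p = 0.318 with an estimated correlation).

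Of 59 G2/M and mitosis genes, 21 rose, 2 fell and 36 did not pass (24 and 2 adjusted over the list alone), with a median of 0.16. The kinetochore genes Nuf2, Cenpf and Ska1 rose by 0.66 ± 0.08, 0.57 ± 0.09 and 0.48 ± 0.08 (camera adjusted p = 0.000411, and adjusted p = 0.318 with an estimated correlation). Of 51 G1/S and DNA replication genes, 16 rose, 5 fell and 30 did not pass (16 and 6 adjusted over the list alone), among them the rises of E2f2 (0.71 ± 0.09), the histone mRNA binding protein Slbp (0.47 ± 0.06) and Dtl (0.44 ± 0.08). The camera adjusted p of the G1/S list was 0.0168, and adjusted p = 0.324 with an estimated correlation. With the most variable probe set per gene neither the G1/S list (adjusted p = 0.0861) nor Cenpf (adjusted p = 0.108) passed, and among genes above background the G1/S list did not (adjusted p = 0.109). Of the 3 probe sets of Cenpf, 1 passed as higher and 0 as lower.

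More genes of the unfolded protein and integrated stress responses rose than fell. Of 50 members of the unfolded protein and integrated stress list, 16 rose, 3 fell and 31 did not pass (18 and 3 adjusted over the list alone), with rises of Trib3 (1.83 ± 0.16, on a probe set that may match more than 1 transcript), the stress sensor Ern1 (1.26 ± 0.10) and Edem1, which acts in the disposal of misfolded proteins (1.08 ± 0.07). Of the 5 probe sets of Ern1, 1 passed as higher and 0 as lower. The camera adjusted p of the list was 0.00727, adjusted p = 0.318 with an estimated correlation and adjusted p = 0.0799 among genes above background alone.

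Among markers of macrophages, megakaryocytes and erythroid cells more rose than fell, while the members that did not pass outnumbered those that did and the list medians were 0.09, 0.10 and 0.02. Of 23 monocyte and macrophage markers 8 rose, 1 fell and 14 did not pass (9 and 1 adjusted over the list alone). The high-affinity IgG receptor Fcgr1 rose at least 15.1-fold, the chemokine receptor Ccr2 by 3.11 ± 0.11 and the adaptor Tyrobp by 2.00 ± 0.10. Of 22 megakaryocyte and platelet markers 9 rose, 1 fell and 12 did not pass (11 and 1 adjusted over the list alone), with rises of the purine receptors P2rx1 (2.26 ± 0.09) and P2ry1 (1.95 ± 0.14) and the platelet glycoprotein Gp9 (1.45 ± 0.06). Both lists had a camera adjusted p of 0.00281, and adjusted p = 0.318 with an estimated correlation. On ranks the megakaryocyte list did not pass (adjusted p = 0.0663). Of 23 erythroid markers 8 rose, 3 fell and 12 did not pass (8 and 4 adjusted over the list alone), with rises of the Rh-associated glycoprotein Rhag (at least 5.14-fold), the erythroid and megakaryocytic transcription factor Gata1 (2.62 ± 0.11) and the membrane skeleton protein Epb42 (at least 3.34-fold). For this list the camera adjusted p was 0.0168, adjusted p = 0.334 with an estimated correlation and adjusted p = 0.0991 on ranks.

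The remaining marker lists did not pass in camera with all genes and arrays. Of 23 mast cell and basophil markers 8 rose and 2 fell, with Il4 up at least 2.7-fold (adjusted p for the list = 0.0537). This list passed without control replicate 4 or TEL-AML1 replicate 2, 3 or 4, with a further quantile normalization, with centring on the array median and among genes above background (adjusted p from 0.00693 to 0.0422). Of 20 endothelial markers 5 rose and none fell, including Plvap, up at least 2.97-fold (0.0957 for the list, and 0.035 among genes above background). Of 19 granulocyte markers 4 rose and 2 fell, with the integrin Itgam up at least 3.32-fold (0.539). Of 28 T and NK cell markers 4 rose and 4 fell, the latter including Gzmb (0.638). Of 20 mature B and plasma cell markers 2 rose and 1 fell, with Tnfrsf13b up by 1.16 ± 0.07 (0.616), and of 31 stromal markers 4 rose and 2 fell, with the collagen gene Col5a1 up by 4.59 ± 0.26 (0.877). Adjusted over the list alone these 6 lists gave the same counts, except that no stromal marker fell. A mean above background was reached by 10 of 23 mast cell and basophil, 9 of 20 endothelial and 5 of 19 granulocyte markers. It was reached by 5 of 28 T and NK cell, 4 of 20 mature B and plasma cell and 8 of 31 stromal markers. Most members of these lists thus lay below background.

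**Figure D3:**
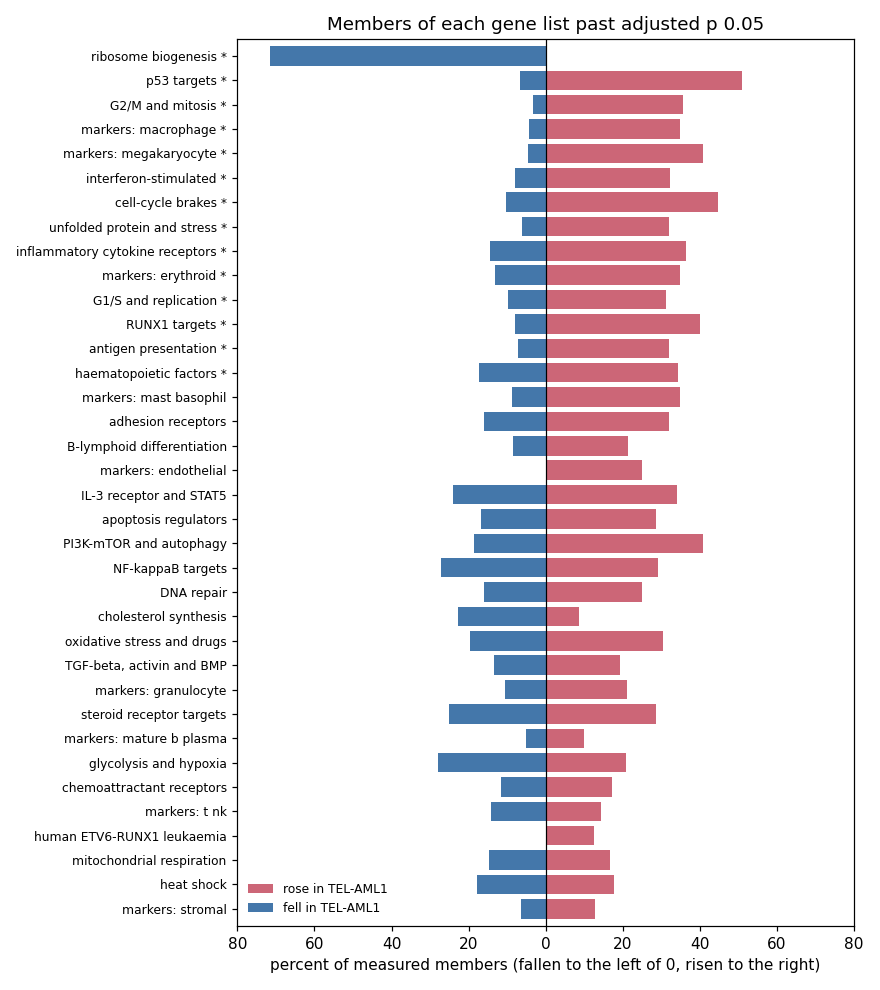
Percent of the measured members of each of the 36 gene lists reported that rose (right of 0) or fell (left of 0) in TEL-AML1 cells past an adjusted p of 0.05, ordered by the camera p, with an asterisk where the camera adjusted p with the preset correlation was under 0.05. The ribosome biogenesis list, at the top, has 40 of 56 members fallen and none risen, and the p53 target list below it has 23 of 45 risen.

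Receptors and transducers for inflammatory cytokines changed in both directions, with more rises. Of 55 measured members 20 rose and 8 fell (22 and 9 adjusted over the list alone). The lipopeptide receptor Tlr1 rose at least 2.88-fold, Tnfrsf13b rose by 1.16 ± 0.07, and the interleukin-18 receptor subunit Il18r1 fell at least 13.1-fold. The camera adjusted p was 0.0101, adjusted p = 0.318 with an estimated correlation and adjusted p = 0.0664 on ranks. Both TNF receptors rose, Tnfrsf1a by 0.70 ± 0.08 and Tnfrsf1b at least 2.21-fold. The receptors for interleukin-6 and interleukin-1 lay below the background level in both groups, with differences of -0.29 ± 0.10 for Il6ra (adjusted p = 0.0431), 0.08 ± 0.08 for Il6st (adjusted p = 0.532) and 0.06 ± 0.14 for Il1r1 (adjusted p = 0.782). The call for Il6ra was lost without control replicate 1 or 2 or TEL-AML1 replicate 1, 3 or 4 (adjusted p up to 0.119), with the mean of all probe sets (0.0718) and with the most variable probe set (0.225).

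Interferon-stimulated and antigen presentation genes rose more often than they fell. Of 62 interferon-stimulated genes 20 rose, 5 fell and 37 did not pass (20 and 6 adjusted over the list alone). The GTPase Ifi47 rose by 2.79 ± 0.14, while the antiviral membrane proteins Ifitm3 and Ifitm2 fell by 2.25 ± 0.13 and 1.83 ± 0.08. The camera adjusted p was 0.00618, and adjusted p = 0.318 with an estimated correlation. Of 28 antigen presentation genes 9 rose and 2 fell, also adjusted over the list alone, with H2-Oa up by 1.71 ± 0.12, the peptide-loading protein Tapbp by 0.83 ± 0.08 and the peptide-trimming enzyme Erap1 by 0.68 ± 0.06. The camera adjusted p was 0.0325, and adjusted p = 0.318 with an estimated correlation. The call was lost without TEL-AML1 replicate 1 (adjusted p = 0.0508) and in other settings, with adjusted p up to 0.0946. NF-kappaB targets went both ways, with 14 risen and 13 fallen of 48 (15 and 13 adjusted over the list alone); Ebi3 rose by 3.46 ± 0.10 (adjusted p for the list = 0.133).

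Single receptors of the TGF-beta and activin family changed in both directions. The type I receptors Acvr1b and Tgfbr1 rose by 1.44 ± 0.10 and 1.12 ± 0.11 (adjusted p = 1.18e-06 and 2.07e-05), and the type II receptor Tgfbr2 fell by 0.41 ± 0.13 (adjusted p = 0.0314). In these directions 1 of 2 probe sets passed for Acvr1b, 3 of 3 for Tgfbr1 and 2 of 3 for Tgfbr2, and 0 the opposite way. The activin type II receptors gave -0.20 ± 0.10 for Acvr2a, below background in both groups, and 0.10 ± 0.09 for Acvr2b (adjusted p = 0.165 and 0.498). The inhibitor of differentiation Id2 rose by 2.69 ± 0.09 and the signal transducer Smad5 by 0.96 ± 0.09. Of 52 members of the list 10 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.46). The call for Tgfbr2 was lost without control replicate 2, 3 or 4 or TEL-AML1 replicate 2, 3 or 4, with adjusted p up to 0.0885, and with the experiment number as a block (adjusted p = 0.0634).

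Single genes of migration and adhesion changed in both directions. The chemokine receptor Cxcr4, which responds to the stromal chemokine Cxcl12, fell by 0.54 ± 0.11 (adjusted p = 0.00252), whereas Cxcr2 rose at least 11.1-fold, Ccr2 rose by 3.11 ± 0.11 and the receptor adaptor Arrb1 rose at least 2.95-fold. Of 52 chemoattractant receptors and regulators 9 rose and 6 fell (camera adjusted p = 0.616). Of 50 adhesion receptors 16 rose and 8 fell, with the tetraspanin Cd81 up by 2.12 ± 0.07 (camera adjusted p = 0.0682, 0.0465 among genes above background and 0.047 without TEL-AML1 replicate 3). Adjusted over the list alone the counts were 9 and 6 for the chemoattractant list and 17 and 11 for adhesion.

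Haematopoietic regulators changed in both directions. Of 58 transcription factors and stem-cell genes 20 rose and 10 fell (22 and 13 adjusted over the list alone), including the rises of Slamf1, Runx1 and Gata1 given above. For this list the camera adjusted p was 0.0496, and adjusted p = 0.318 with an estimated correlation. This call was lost with the experiment number as a block (adjusted p = 0.0708), without control replicate 1, 2 or 4 or TEL-AML1 replicate 1 (adjusted p from 0.0505 to 0.0898), and with a further quantile normalization, array quality weights or ranks (adjusted p from 0.0576 to 0.211). Of 25 described RUNX1 targets 10 rose and 2 fell (11 and 2 adjusted over the list alone), and 21 of these members also stand in another list. The lipoxygenase Alox12 rose at least 5.42-fold and the integrin Itgal by 1.68 ± 0.13, while Runx3, a relative of Runx1, fell by 2.13 ± 0.10 (camera adjusted p = 0.0325, and adjusted p = 0.318 with an estimated correlation). The call for the RUNX1 targets was lost with the most variable probe set per gene (adjusted p = 0.0566) and on ranks (adjusted p = 0.0991). Genes described as high in human leukaemia with this fusion mostly did not pass, with 2 of 16 risen, also adjusted over the list alone: Epor, the erythropoietin receptor, by 0.75 ± 0.12 and Tusc3 by 0.30 ± 0.09 (camera adjusted p = 0.643). Only 6 of the 16 had a mean above background, so the list gives little information on the others. The call for Tusc3 was lost without control replicate 2 or TEL-AML1 replicate 2 or 3, with adjusted p up to 0.0627.

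B-lymphoid genes included a few large rises. Blnk, the linker of the B-cell receptor pathway, rose at least 8.87-fold, the scaffold protein Bank1 by 2.43 ± 0.12 and the B-cell receptor subunit Cd79b by 1.69 ± 0.09. Of 47 members 10 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0751). The list passed among genes above background (adjusted p = 0.0247) and without TEL-AML1 replicate 3 (adjusted p = 0.0499). Of 50 genes of the interleukin-3 receptor and STAT5 response 17 rose and 12 fell (18 and 12 adjusted over the list alone), and Csf2rb2, a receptor subunit for interleukin-3, rose by 2.50 ± 0.09 (camera adjusted p = 0.0977, and 0.0431 without TEL-AML1 replicate 4).

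The other process lists did not pass in camera. Apoptosis regulators (12 risen and 7 fallen of 42, adjusted p = 0.109) included a rise of Casp4 by 2.83 ± 0.11, DNA repair genes (14 and 9 of 56, 0.409) a rise of Chek2 by 1.49 ± 0.07, and oxidative stress and drug metabolism genes (14 and 9 of 46, 0.454) a rise of Me1 by 1.52 ± 0.07. In PI3K-mTOR signalling and autophagy (22 and 10 of 54, 0.133) Igf1r fell by 1.37 ± 0.07. Among steroid receptor targets (8 and 7 of 28, 0.547) Tgm2 rose at least 12.7-fold, on a probe set that may match more than 1 transcript. Cholesterol genes (3 and 8 of 35, 0.409) included a rise of Npc2 by 0.71 ± 0.07, glycolysis and hypoxia genes (9 and 12 of 43, 0.616) a fall of Slc2a3 by 0.97 ± 0.08, also on such a probe set, mitochondrial respiration genes (9 and 8 of 54, 0.643) a fall of Cox5a by 0.43 ± 0.06, and heat-shock genes (5 and 5 of 28, 0.841) a fall of Hspa9 by 0.56 ± 0.06. Adjusted over the list alone, the counts changed for DNA repair (15 and 10), oxidative stress (14 and 10), PI3K-mTOR (23 and 12), steroid receptor targets (9 and 8) and mitochondrial respiration (9 and 9).

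Of the 37 lists, 13 passed as higher and 1 as lower in TEL-AML1 cells with the preset correlation of camera, and none with an estimated correlation, where 4 had an unadjusted p under 0.05. For antigen presentation the estimate was -0.005, below the preset 0.01, so a larger correlation within the list does not account for every lost call. Fry, which tests a list without setting it against other genes, called 28 lists. Camera on ranks kept 8 of the 14 calls and lost those for RUNX1 targets, antigen presentation, haematopoietic factors, inflammatory receptors, megakaryocytes and erythroid cells. The calls for RUNX1 targets, antigen presentation, G1/S, stress and haematopoietic factors were each lost in at least 1 setting of the gene-level fit. Among the lists reported, the median and the mean of the members had opposite signs in the lists for adhesion, DNA repair, oxidative stress, TGF-beta signalling, steroid receptor targets, chemoattractant receptors, granulocytes, mature B cells and stroma, and camera's direction was opposite to the mean for respiration and stroma, none of which passed. Control probe sets gave a measure of RNA integrity. The log2 difference between 3 prime and 5 prime probe sets of Actb was 0.310 ± 0.035 (SD, n = 4) in control and 0.376 ± 0.027 in TEL-AML1 cells (exact permutation p = 0.0571, Benjamini-Hochberg value 0.114), and that of Gapdh was -0.077 ± 0.014 and -0.075 ± 0.030 (exact permutation p = 0.886), where 0.0286 is the smallest p that 4 against 4 arrays can give. At that limit neither gene could pass alone after adjustment over both, so a difference in RNA integrity is not excluded.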

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

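The tests in this part, including the splits of the arrays, were chosen or written down after the results had been seen.

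For 96 named genes, the 4 arrays of each group were searched for a single array far from the others, and 11 of 192 sets held one, where chance gives about 1 in 20. TEL-AML1 replicate 1 was the distant array in 6 of them: Itgal at 9.02 (next array 8.49), Id2 at 9.79 (next 9.50), Tgfbr1 at 10.02 (next 9.56), Acvr2a at 4.48 (next 4.33), Il4 at 5.71 (next 6.34) and Epb42 at 6.39 (next 6.57). In control replicate 4, Cd81 lay at 7.27 (next 7.37), Cdkn2c at 10.27 (next 10.10) and Plvap at 4.40 (next 4.87). Igsf5 lay at 8.61 in control replicate 1 (next 9.16) and Chek2 at 6.52 in control replicate 2 (next 6.64). The array quality weight of TEL-AML1 replicate 1 was 0.50, the lowest of the 8, and without this array 5005 genes passed and 623 changed at least 2-fold.

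Probe sets that carry no gene name here also separated the groups. Of 9160 such probe sets 896 passed, 70 of them higher by at least 2-fold in TEL-AML1 cells and 17 lower by at least 2-fold.

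The count of 5374 genes past the threshold was reached by 1 of the 35 ways to split the 8 arrays 4 against 4, the real one, and the highest count of any other split was 0; for the 677 genes changed at least 2-fold it was likewise 1 of 35, with 0 as the highest other. Chance assignment of arrays can be excluded for both counts at the 5% level, where 1 of 35 is the smallest share possible, only if all 8 arrays are exchangeable. If arrays with the same experiment number shared handling, fewer splits would apply, too few to reach that level. The splits also restate the array correlations, which were at least 0.9956 within groups and at most 0.9872 between them. They do not show what made the groups differ, because the labels do not say whether arrays came from separate clones or cultures. For the 14 lists the splits do not exclude chance assignment, since 2 of the 35 gave as many. The highest other split, which exchanged control replicate 3 with TEL-AML1 replicate 3, gave 15. That split left 3 of the 4 arrays of each group together, and the splits with 2 arrays of each group on either side gave 0 to 6 lists.

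The eosinophil granule genes Prg2 and Epx were far higher and the granzymes Gzmb and Gzmc far lower in TEL-AML1 cells. To lower the 8 most strongly reduced genes by dilution, other cells would have had to replace a median of 94.9% of the RNA, counted down to the background level, which argues against a minor admixture for these 8 falls. That share follows directly from the fold changes of genes chosen for their falls, so it is not a separate test. For the rises, admixture of mature eosinophils stays open on these values, although the samples came from a cell line kept under drug selection. The genes Ccr3, Il5ra, Alox15, Ltc4s and Cd24a, picked after the values of some had been seen, had a median difference of -0.10. However, 4 of these 5 lay below background in both groups. The remaining gene, Ltc4s, fell from 5.59 to 4.77 (adjusted p = 0.00139), which goes against admixture but is a single gene near the background level. A difference between clones unrelated to the fusion also cannot be told apart from an effect of the fusion, because 0 groups have labels that name more than 1 clone, and an effect of the fusion itself remains an untested hypothesis.

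Of 45 targets of p53, 23 were higher in TEL-AML1 cells, 3 were lower and 19 did not pass, and the list passed in camera with the preset correlation but not with an estimated one (adjusted p = 0.318). A trend of differences with expression level is argued against as the whole cause, since the list median of 0.30 stood at percentile 100 of 10000 random lists matched on mean expression, whose central 95% ran from -0.12 to 0.05. Zeocin, a DNA-cleaving drug of the bleomycin family that the labels tie to the TEL-AML1 clones, may have raised them; it cannot be told apart from the fusion, because 0 groups hold arrays both with and without the drug. An effect of the fusion on these genes remains open and untested.

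Of 56 ribosome biogenesis genes 40 were lower and none higher, and this list too passed with the preset correlation but not with an estimated one (adjusted p = 0.318). Their median of -0.34 stood at percentile 0 of 10000 matched random lists, which argues against a trend with expression level. A lower share of cells in G2/M in the TEL-AML1 cultures would lower the G2/M genes too. Yet the mean of that list was higher by 0.128 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give), which argues against such a lower share. It does not decide on fewer cycling cells, because cells held in G2/M would keep these transcripts. The mean of the G1/S and replication list was also higher, by 0.093 (exact permutation p = 0.0286), which by itself goes against fewer cycling cells. The mean of the cell-cycle brakes was higher by 0.324 (exact permutation p = 0.0286), though the median difference of their members was 0.06. That higher mean by itself would go with fewer cycling cells. Fewer cycling cells, the fusion, the difference between clones and the drug remain open.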

How the results depend on the processing

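The alternatives were fixed before the data were examined except the omission of probe sets that may match several transcripts, 2-fold counts over all probe sets, and leaving out arrays for the Etv6 and Runx1 probe sets and the control probe sets. Over all settings with genes as the unit, 4551 to 5730 genes passed and 546 to 763 changed at least 2-fold; with all probe sets as the unit the counts were 9667 and 1186, because more features were tested. Leaving out 1 array in turn gave 4551 to 5191 genes. With the experiment number as a replicate block 5152 genes passed (2529 higher and 2623 lower), 4912 of them shared with the 5374 in the same direction, 677 changed at least 2-fold and 13 lists passed. The main fit, fixed beforehand, did not take the numbers as pairs. Deviations of arrays with the same number correlated between -0.06 and 0.09 across genes, and 3 of the 8 arrays correlated best with their own number. For the hybridisation spike-in controls, mean deviations of arrays with the same number correlated at 0.918. Pairing by number was among the 2 closest of 24 pairings there (exact permutation p = 0.0833). For the labelling controls the correlation was 0.565, and pairing by number was among the 5 closest (exact permutation p = 0.208). Neither passes 0.05, but shared handling of arrays with the same number is not excluded. The sample titles, which alternate between the groups in the order of the experiment number, would go with it.

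Of 14 lists that passed, 0 passed with an estimated correlation and 8 with camera on ranks, while fry called 28 of 37; 9 of the 14 passed in all settings run with the preset correlation on the log2 values. Of 96 named genes, 88 kept direction and side of the threshold in every setting that gave them a value; 6 have none among genes above background, where their mean lies below that level. The exceptions were Tgfbr2, Il6ra, Tusc3 and Cenpf, which lost their call in at least 1, Tmsb10, at 1.23 with all probe sets and -0.14 without probe sets that may match several transcripts, and genes that never passed: Il1r1 ranged from -0.05 to 0.17 when 1 array was left out, Acvr2b was -0.03 with the mean of all probe sets and -0.13 with the most variable one, and Il6st 0 and -0.20. Lists far from passing also changed direction, given here by adjusted p. With fry these were respiration (0.733) and stromal markers (0.67); with the most variable probe set chemoattractant receptors (0.895), respiration (1), mature B cells (0.895) and stromal markers (0.895); with genes above background stromal markers (0.3). The cause was not tested. When 1 array was left out, adjusted p ranged from 0.348 to 0.953 for respiration and from 0.619 to 0.951 for stromal markers, with a change of direction without control replicate 1 (stromal) or TEL-AML1 replicate 4 (respiration). Of the 8 probe sets of Etv6 and Runx1, 7 or 8 passed when 1 array was left out, the one lost being the Runx1 probe set with the smallest difference, and 8 with the block. The group difference between 3 prime and 5 prime probe sets of Gapdh ranged from -0.012 to 0.009, around its value of 0.002, and that of Actb from 0.057 to 0.082. Signal over background limits the small differences: receptors such as Il6st and Il1r1 lay below 4.79 in both groups.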

Other observations

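Further genes, picked after their values had been seen and not tested as groups of their own, were among those that passed. The IgG receptor Fcgr3 rose at least 3.89-fold and Fcgr2b by 2.33 ± 0.14 on the log2 scale. The CD200 receptor relatives Cd200r3 and Cd200r4 rose at least 6.11-fold and at least 3.43-fold, and the Schlafen genes Slfn4 and Slfn2 at least 14-fold and by 3.10 ± 0.09. The IgE receptor subunit Ms4a2 rose at least 7.65-fold, the eosinophil granule protein Prg3 at least 4.41-fold and the cytokine Il15 at least 6.17-fold. Ms4a2 and Cd200r3 also stand in the mast cell and basophil list, which did not pass in camera with all genes and arrays (adjusted p = 0.0537).

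Falls among genes picked in the same way included those of the integrin Itgae (-3.62 ± 0.19, on a probe set that may match more than 1 transcript), the inhibitory receptor Havcr2 (-3.45 ± 0.18), the NK receptor Cd244a (-3.54 ± 0.26) and the transcription factor Stat4 (-2.00 ± 0.19). Itgae also stands in the adhesion list, which did not pass in camera with all genes and arrays (adjusted p = 0.0682). Ets1 fell at least 2.77-fold, and Fut7, which makes selectin ligands, fell by 4.23 ± 0.13. The list of T and NK cell markers fixed beforehand did not pass in camera, with 4 of 28 members risen and 4 fallen, a median of -0.06 and an adjusted p of 0.638. Only 5 of these 28 had a mean above background, so the median rests mostly on genes near the floor. The perforin gene Prf1 lay below background in both groups, with a difference of 0.09 ± 0.07 that did not pass.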
